A study of Mus musculus with 50 samples.

How the data were processed

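Single haematopoietic stem cells (HSCs) carrying GFP were each transplanted with unlabelled competitor marrow into irradiated mice, and blood-forming cells of the recipients were sequenced cell by cell 1, 4 or 12 months later. The labels list 50 samples, 10 at 1 month, 26 at 4 months and 14 at 12 months. Per the labels' protocols, cells were enriched for c-Kit, sorted singly into tubes by surface markers or GFP, barcoded at reverse transcription, amplified and then pooled into libraries by a modified Smart-seq2 (STRT-seq) method that enriches the 3' ends of transcripts.

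The deposited matrix holds whole-number counts per gene and cell, with no normalization. Per the submitters' processing notes, Trimmomatic 0.36, HISAT2 2.1.0, HTSeq 0.9.1 and the mouse build GRCm38 were used. Whether the counts are of reads or of molecules is not given in the sources used here. The median was 12 counts per detected gene in a cell, and amplified copies are not independent molecules. Intervals on shares and summed counts below therefore cover counting error only, and those on summed counts can be too narrow even for that. A bootstrap interval given below resamples libraries instead. Of the 19224 gene symbols, 19071 matched the GENCODE mouse release 21 annotation of GRCm38, from which positions were taken.

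The cells are named by library and barcode, and 0 of the 4271 names used hold a sample title. The columns of 1 further library, with 17 cells, were not used here. They had been part of an earlier run, in which the cluster borders differed, the HSC-like share lay outside the interval given below and an erythroid class was named. A list of 4288 sequencing runs gives names for 2133 of them, and 2116 of those names match a cell. That list names no sample, and runs were not traced to samples. No table used here ties a cell to a sample, a month, a tissue or a sort gate, and none was inferred. The whole matrix was therefore treated as 1 pooled sample. The planned comparisons between months and between spleen and marrow, and the tests chosen for them, were not run. No p-value, standard error or count of changed genes was made from cells. Libraries are not replicates of any group, so values over libraries are given as a median and a range.

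Cells with at least 1000 detected genes and at most 10% mitochondrial counts were kept, which left 4185 cells; 76 cells fell under the gene minimum and 13 were over the mitochondrial limit. No doublet caller was run because cells were sorted singly. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were selected with scanpy 1.11.5, and 30 components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1 with seed 0 gave 24 clusters. Components were computed with numpy 2.4.6 and neighbours by exact search with scikit-learn 1.9.0, under Python 3.11.15 with scipy 1.17.1 and pandas 2.3.3.

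The cell filter, the cluster settings, 26 pathway lists and 14 marker lists (747 genes, 733 of them in the matrix) were chosen before the data were examined. The rule that turns marker lists into names, and the choice of which classes and clusters to compare, were made after clusters had been seen, an earlier trial clustering included. A lineage name needed a mean log2 ratio of its markers of at least 2 over the other clusters, at least 3 markers detected in 25% of cells, and at least as many of its markers as of any other class among the top 10 genes by fold. A cycling cluster had at least 3 cell cycle genes among its top 10. An HSC-like cluster had the HSC markers as its highest-scoring list, at least 8 of them detected, and no more markers of another class than of its own among its top 10. That last condition was the first one written. It was then loosened to allow 1 more marker of another class once it was seen to leave 2 clusters with stem cell genes unnamed, and later restored because the looser form had been fitted to the outcome. Both versions are reported. Unnamed clusters and sub-clusters were chosen for comparison by a leading gene, as the cluster in which that gene stood highest among the top 10. The largest cluster with the gene had been taken at first, and that choice is reported for Cd34.

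Groups of cells were compared by their summed counts as CPM (counts scaled to one common total), with a pseudocount of 1 CPM on the log2 scale. For each list of at least 5 members at a log2 CPM of at least 4 in either group, the median log2 ratio was set against 10000 random lists of as many genes matched on mean level in 20 bins, and a list was called higher or lower when outside the 2.5 to 97.5 percentile range. Genes used for clustering were left out of the lists. The clusters were still made from the same cells, and genes of a list move together, so percentiles describe these cells and are not tests. A direction was also counted over libraries with at least 5 cells of both groups. Genes were named by size: the 10 largest ratios each way among genes at the same minimum level, counted in at least 75% of the libraries of the higher group, without predicted genes; 3 members of each called list; and 12 genes named whatever their values. Shares have exact Clopper-Pearson 95% intervals and summed counts exact Poisson 95% intervals. For shares of cells with a count, each cell was also thinned to 10000 counts. Simulated sums were made for the cycling against HSC-like comparison, with 200 genes changed 2-fold over 7274 genes. The median log2 ratio was 0.98 for raised and -1.00 for lowered genes. There, 20 of 20 raised and 20 of 20 lowered lists were called, and 8 of 200 unchanged lists fell outside the range. Simulated genes varied by counting error only, each changed list held only genes changed the same way, and fewer random lists were drawn. The simulation therefore says nothing about lists whose genes move together. Other cell filters, resolutions, a second seed, a library left out before clustering, a lower lineage score, equal weighting of cells, a pseudocount of 10 CPM, thinning, lists with the clustering genes, lists without naming markers, a left-out library and the looser naming were tried.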

Results

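Transcriptomes of 4271 sorted cells from recipients of single HSCs were examined. The 50 labelled samples comprised 10 at 1 month, 26 at 4 months and 14 at 12 months after transplantation, of which 5, 4 and 6 were labelled as marrow with spleen and the others as marrow alone. The cells came in 67 libraries of 22 to 92 cells and carried 624386060 counts in all. The 4185 kept cells had a median of 122013 counts, 4186 detected genes and 1.65% mitochondrial counts. Total counts per library ranged from 1665151 to 26184494. Cells were not assigned to months or tissues here, so how the stem cell compartment changes with time after transplantation was not addressed. The values describe all cells together, with no replicates.

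Cells resembling HSCs formed the largest class. It held 2099 of 4185 cells, or 50.2% (exact 95% interval 48.6 to 51.7), in clusters with Procr, which encodes the HSC surface protein EPCR, at 288 CPM and the stem cell transcription factor genes Mecom and Hlf at 161 and 231 CPM. A further 2 clusters with 640 cells, 15.3% of the total (14.2 to 16.4), stayed unnamed because a marker of another class stood among their leading genes. Procr was at 252 CPM in the first of them, cluster 1, and at 290 CPM in the other, cluster 11. With both included the HSC-like share was 65.4%. Cluster 8, with 212 cells or 5.07% and Procr at 283 CPM, is in neither share because stromal or endothelial markers scored highest in it. The HSC-like share thus depends on the naming rule, which was set after clusters were seen. It also moved with the clustering while the rule was unchanged. It was 38.9% at the lower cluster resolution and 61.7% with a second seed. The sorting gates can set all shares given here.

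**Figure D1:**
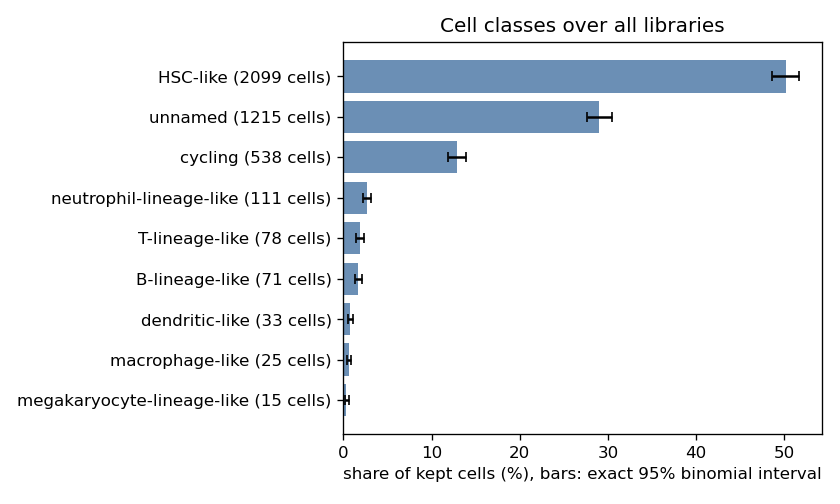
Share of the 4185 kept cells in each class, in percent, with exact 95% binomial intervals. HSC-like cells made up 50.2%, unnamed cells 29.0% and cycling cells 12.9%, and each other class stayed at 2.65% or below.

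Over the 67 libraries the HSC-like share had a median of 52.5% and ranged from 0 to 84.5%. Cycling cells, with cell cycle genes leading their clusters, made up 12.9% (11.9 to 13.9) of cells, or 538 cells, with a library median of 10.7% and a maximum of 51.4%. Smaller classes carried lineage markers. There were 111 neutrophil-lineage-like cells (2.65%, 2.19 to 3.19), 78 T-lineage-like cells (1.86%, 1.48 to 2.32), 71 B-lineage-like cells (1.70%, 1.33 to 2.14), 33 dendritic-like cells (0.789%, 0.543 to 1.11), 25 macrophage-like cells (0.597%, 0.387 to 0.881) and 15 megakaryocyte-lineage-like cells (0.358%, 0.201 to 0.590). Without the library that held most of the class, the B share was 0.731%, the macrophage share 0.169% and the megakaryocyte share 0.170%.

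**Figure D2:**
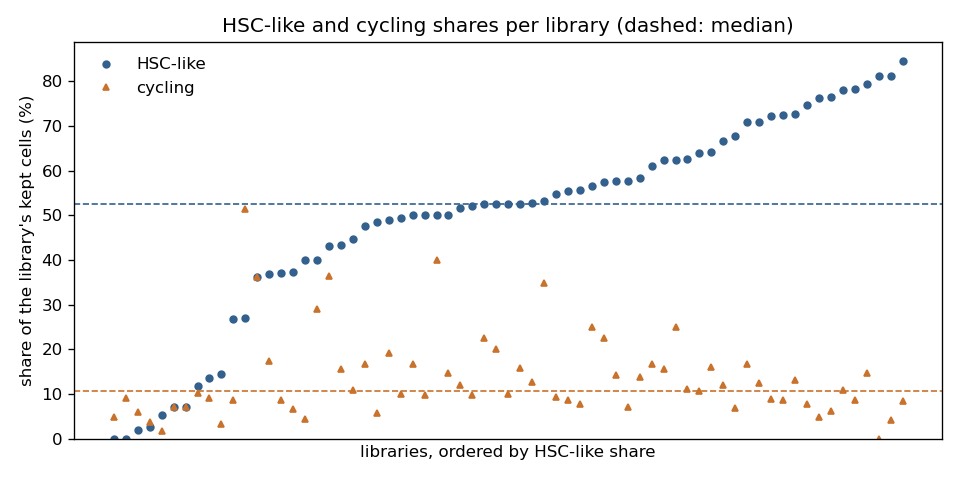
HSC-like (circles) and cycling (triangles) shares of the kept cells of each of the 67 libraries, in percent, ordered by HSC-like share. The dashed lines are the medians, 52.5% and 10.7%.

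Cycling cells expressed less of the stem cell program than HSC-like cells. Of 17 tested HSC identity genes 16 were lower, with a median log2 ratio of -0.58 and a lower list median in 48 of 48 libraries. Because HSC-like clusters were named by HSC markers, Procr, Hlf and Mecom among them, the naming can set part of this difference. With all naming markers left out, the list median was -0.78, so it does not rest on those markers alone. Procr was at 93.7 CPM in cycling cells (Poisson interval 92.0 to 95.4) and at 288 CPM in HSC-like cells (286 to 290), a log2 ratio of -1.61, and lower in 48 of 48 libraries. Procr lies on chromosome 2 at 155751117 to 155755471 of GRCm38. A Procr count was present in 74.0% of cycling and 90.2% of HSC-like cells, and in 42.3% and 72.5% of them after thinning, against 3.17% of thinned B-lineage-like cells. Median depths before thinning were 201908, 123089 and 33179 counts. Hlf had a log2 ratio of -0.79 (46 of 48 libraries) and Mecom of -0.45 (36). Genes raised in aged HSCs were lower at a median of -0.85 (13 of 13 members, 42 of 48 libraries). The lectin gene Clec1a was at -1.42 and the junction gene Jam2 at -1.51. This list holds Slamf1, an HSC marker gene, and HSC-like clusters were named by HSC markers. The naming can thus set part of the aged HSC difference, also in later comparisons with HSC-like cells. Quiescence genes stood at -0.64 in 47 of 48 libraries. Among them were Txnip at -1.38 and Pdzk1ip1 at -1.12. Cdkn1c, which encodes the cell cycle inhibitor p57, was at -1.10 in 35 of 48 libraries. Because the cycling class was named by cell cycle genes, its naming can set part of the quiescence and Cdkn1c differences.

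Genes of DNA replication had a median log2 ratio of 2.16 in the cycling class and those of mitosis of 3.84, which its naming by cell cycle genes sets. Outside the cell cycle, oxidative phosphorylation genes were higher at a median of 0.37 (36 of 37 members, 47 of 48 libraries), with Cycs, which encodes cytochrome c, at 0.98 and Cox5b at 0.71. Ribosome biogenesis and MYC target genes were higher at 0.41 in 42 of 48 libraries, with Srm, the spermidine synthase gene, at 0.93 and Cad, of pyrimidine synthesis, at 1.23. The other lists below their random range were inflammation and NF-kB at -0.93 (43 of 48 libraries), interferon response at -0.68 (41), HOX genes at -0.56 (44), p53 targets at -0.52 (37), autophagy and lysosome at -0.37 (46) and cytosolic ribosomal proteins at -0.10 (42). The HOX list had only 6 tested members, and it shares Hoxb5 with the HSC identity list. Some of its members are also naming markers, and no value without them is given for this comparison. The naming can thus set part of the HOX difference, also in the comparisons with HSC-like cells below. In all, 13 of 21 tested lists lay outside their random range.

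HSC-like cells were not uniform. Cluster 2, with 382 cells, had Mllt3 and Sult1a1 among its leading genes, and cluster 6, with 264 cells, was led by Cd34 and Vldlr. Aged HSC genes had a median log2 ratio of -0.92 in cluster 6 relative to cluster 2, with 15 of 15 members lower and a lower median in 12 of 12 libraries. The endocytosis gene Ehd3 stood at -1.99 and the receptor gene Neo1 at -3.60. HSC identity genes were lower at -0.55 in 12 of 12 libraries. The clusters were chosen by leading genes, and Mllt3 is itself a naming marker. HSC markers had a mean log2 ratio over the other clusters of 0.58 in cluster 2 and 0.065 in cluster 6. Clec1a, an aged HSC gene, is among the leading genes of cluster 2. The choice of clusters can thus set part of both differences, also for cluster 3 below. Slamf1, which encodes the HSC marker CD150, was at 21.6 CPM in cluster 6 and 64.6 CPM in cluster 2, and Procr was at 184 and 429 CPM. Mecom and Hlf differed little, at -0.13 and 0.08. Cdkn1c had a log2 ratio of -1.24 in 9 of 12 libraries, and Vwf, a platelet gene used for clustering, of -2.30 in 8.

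Interferon response genes were lower in cluster 6 at -0.62 (12 of 12 libraries), with the GTPase gene Gbp2 at -1.07. MHC class I genes were at -0.28 (11 of 12), with H2-D1 at -0.62, inflammation genes at -0.50 (9), p53 targets at -0.27 (8), quiescence genes at -0.31 (11), autophagy genes at -0.22 (10) and HOX genes at -0.33 (7). Higher in cluster 6 were DNA replication genes at 0.51 (10 of 12), with the helicase gene Mcm2 at 1.06, ribosome biogenesis genes at 0.29 (12) and oxidative phosphorylation genes at 0.16 (10). Flt3, a receptor gene of multipotent progenitors that was used for clustering, was at 59.1 CPM against 11.7 CPM and higher in 12 of 12 libraries. Of 21 tested lists 12 lay outside the random range. After thinning, the quiescence list (-0.18) and the autophagy list (-0.05) did not, nor did the HOX list with its members used for clustering (-0.12) or without naming markers. Cluster 3, with 361 cells and Cd34 lower among its leading genes, also had aged HSC genes at -0.91 and HSC identity genes at -0.69 relative to cluster 2, in 8 of 11 libraries each. Its interferon genes were at -0.23, and its oxidative phosphorylation, inflammation, p53 and HOX lists lay inside the random range, unlike those of cluster 6.

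**Figure D3:**
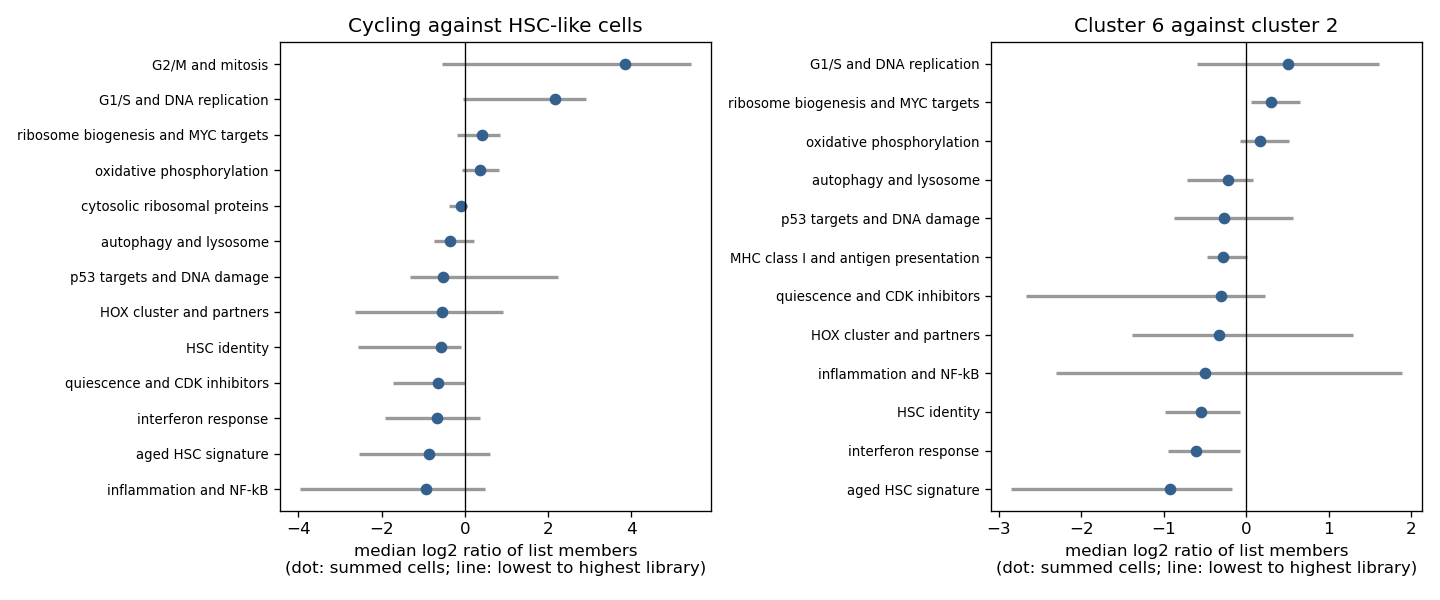
Median log2 ratio of the members of each called list in cycling against HSC-like cells (left) and in cluster 6 against cluster 2 (right). Dots are values from summed cells and lines run from the lowest to the highest library; HSC identity stood at -0.58 on the left and aged HSC genes at -0.92 on the right.

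Cluster 10, with 202 HSC-like cells, was led by interferon-induced genes such as Ifit1 and Ifit3. Interferon genes not used for clustering were higher there than in the other 1897 HSC-like cells. Their median was 0.89 (22 of 22 members, 12 of 12 libraries), with the nucleic acid sensor gene Zbp1 at 1.30. Usp18 and Ifi44 of this list are themselves among the leading genes of the cluster. This difference was thus largely set by choosing an interferon-led cluster from the same cells. Procr was at 321 CPM against 284 CPM and higher in 6 of 12 libraries. Targets of p53 were at -0.46 in 12 of 12 libraries, with Bax at -0.64 and Sesn1 at -0.73, though this list lay inside the random range after thinning (-0.28) and without the library with most of these cells (-0.41). Fatty acid and cholesterol genes were at 0.21, higher in 4 of 12 libraries only, and inside the random range in 3 alternatives, such as thinning (0.17). Cytosolic ribosomal protein genes had a positive median of 0.10 (7 of 12 libraries) that lay below nearly all random lists of like expression (percentile 1.89), so they were called lower, but not with equal weights (0.07).

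Cluster 4, with 354 HSC-like cells, was led by immediate early genes such as Nr4a1 and Fos. Relative to the other 1745 HSC-like cells, DNA replication genes were lower at -0.48 (17 of 17 members, 22 of 26 libraries), with Cdc6 at -0.90. Aged HSC genes were higher at 0.36 (18 of 26) and inflammation genes at 0.39 (13 of 26). Socs3 of the inflammation list, which encodes a cytokine signalling inhibitor, was at 81.0 CPM against 20.7 CPM. Cluster 4 was chosen by a leading gene from these same cells, so that choice can set part of its list differences. Epigenetic regulators stood at -0.19 and oxidative phosphorylation genes at -0.10, in 23 of 26 libraries each, fatty acid genes at -0.20 (19) and autophagy genes at 0.07 (11). The autophagy list turned to -0.0057 after thinning. The epigenetic list lay inside its random range in 3 alternatives, such as equal weights (-0.14), the oxidative phosphorylation list after thinning (-0.08) and with equal weights (-0.07), and the fatty acid list without the main library (-0.20). Cells of cluster 4 had a median of 88597 counts.

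Cluster 12, with 125 cells, stayed unnamed, with a best lineage score of 1.86. Dntt of the lymphoid program and the protease genes Prss34 and Mcpt8 led it together. HSC identity genes were at -2.59 relative to HSC-like cells and HOX genes at -1.31, each lower in 7 of 7 libraries. Aged HSC genes were at -2.69 in 6 of 7, and Procr was at 45.8 CPM against 288 CPM. DNA replication genes were at 1.54 in 7 of 7 libraries and mitosis genes at 2.94 in 5. Granulocyte and monocyte priming genes, with 5 tested members, were at 1.64 over all cells. Their library medians ran only from -1.27 to 1.15 and were higher in 4 of 7 libraries. The myeloid transcription factor gene Cebpa was at 3.76, also higher in 4 of 7. Lymphoid priming genes were at 0.72 (5 of 7), with Ikzf1 at 1.38. Interferon genes were at -0.88 (6 of 7) and MHC class I genes at -0.48 (5). Cluster 17, with 81 cells led by the granule genes Ctsg, Mpo and Elane, had priming genes of granulocytes and monocytes at 1.70 over all cells but only at 0.05 and 0.35 in the 2 libraries that held both groups, with Gfi1 at 1.98, and HSC identity genes at -0.69 in 1 of 2. Its cells had a median of 26314 counts and 31 of them came from 1 library.

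Cluster 18, with 80 cells led by erythroid genes, scored under the minimum for a lineage name. It made up 1.91% of cells (1.52 to 2.37), and 1.04% without the library that held 37 of them. Erythroid genes not used for clustering had a median log2 ratio of 4.86 over HSC-like cells in 3 of 3 libraries. Tspo2, Ermap and Sphk1 of this list are among the genes that led the cluster. The value thus largely restates how the cluster was chosen. Over all genes, Atp1b2 of the sodium pump was at 6.51 and Add2 of the membrane skeleton at 5.92. Mitosis genes were at 3.57 (19 of 20 members), DNA replication genes at 2.22 (25 of 25), ribosome biogenesis genes at 1.00 (28 of 28) and oxidative phosphorylation genes at 0.71, while HSC identity genes were at -3.54 and HOX genes at -3.54, in 3 of 3 libraries each. The median over all tested genes was -0.19 in this comparison. Neutrophil-lineage-like cells had ribosomal protein genes at -1.32 (47 of 47 members lower), ribosome biogenesis genes at -1.02, MHC class I genes at -1.09 and mitosis genes at 2.98. These directions held in 3 of 3 libraries each, and the median over all tested genes was -0.38. All 3 are among 5 neighbouring libraries, described below, in which HSC-like cells carried high neutrophil and erythroid markers. Megakaryocyte-lineage-like cells, 8 of 15 from 1 library, had Gata1, of the erythroid and megakaryocyte program, at 4.36 and mitosis genes at 2.36. Without that library the mitosis genes were at -0.34. The megakaryocyte and platelet list of this class, with 8 tested members, was at 0.41 and inside its random range.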

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

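The list alternatives, the lists on other clusterings, the second seed, the left-out libraries, the lower lineage score and the looser naming were chosen after the data had been seen. The share of HSC-like cells moved beyond its counting interval in 7 of 8 alternatives, all but the lower lineage score. From 50.2% it went to 62.8% with at least 500 genes and no mitochondrial limit, 60.0% with at least 2000 genes, 38.9% at Leiden resolution 0.5, 57.3% at resolution 2, 61.7% with seed 1, 59.5% without the smallest library and 65.4% when 1 more marker of another class was allowed. The last adds 2 clusters. For the others the cause was not tested. Cycling cells went from 12.9% to 9.06% with at least 500 genes, 14.0% with at least 2000 genes and 10.7% at resolution 0.5, where the cause was not tested. An erythroid class was named with at least 2000 genes (2.15%), at resolution 2 (1.53%), with seed 1 (4.44%) and with a lineage score of at least 1.5 (1.91%). Dropping the Y-linked genes was void, since 0 of them were used for clustering. A library minimum of 10 cells left the same 67 libraries.

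Of 1001 values of called lists under alternatives, 922 had the same call, 70 lost it with the same sign and 9 changed sign. Only the lists of cycling against HSC-like cells were also computed on the classes of the other 6 clusterings, where 77 of 78 values had the same call and p53 targets lost it (-0.41 with at least 500 genes). All other list values rest on the reported clusters. For cluster 12, calls lost in at least 1 alternative were quiescence, oxidative phosphorylation and autophagy. For cluster 17 they were interferon, MHC class I and ribosomal proteins, and for cluster 18 lymphoid priming, interferon, MHC class I and inflammation. Calls were also lost by 8 values for B-lineage-like, 7 for neutrophil-lineage-like, 4 for T-lineage-like and 4 for megakaryocyte-lineage-like cells. The same held for 3 values of cluster 3 against cluster 2 and 1 of the Jchain cluster. The lists behind these further values are not named here. With naming markers left out, HSC identity genes in cycling cells were at -0.78. In the megakaryocyte comparison 5 called lists became 8 with cells weighted equally, 9 after thinning and 3 with the further clusters counted as HSC-like, and mitosis genes turned to -0.34 without the main library. With the clustering genes kept, called lists went from 9 to 14 for the Jchain cluster and from 7 to 13 for the early gene cluster, as more members were tested, heat shock genes in the Jchain cluster went to 0.039, and quiescence genes in cluster 3 against cluster 2 to 0.62. For the interferon cluster 4 called lists became 2 with equal weights and 2 after thinning. With equal weights and after thinning, autophagy genes in neutrophil-lineage-like cells went to -0.053 and -0.084, and DNA replication genes in B-lineage-like cells to -0.54 and -0.61. Erythroid genes in T-lineage-like cells went to -0.040 with equal weights and autophagy genes in the early gene cluster to -0.0057 after thinning. Where no cause is given, the cause was not tested. The month and tissue comparisons and their alternatives were not run, since cells were not tied to a month or tissue here. No paired analysis was possible because no result comes from a test between groups of samples.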

Other observations

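Cluster 20, with 77 cells, was led by Jchain, Mzb1 and Sdc1, genes of antibody-secreting cells, for which no list had been fixed. Relative to HSC-like cells, HSC identity genes were at -3.68 and HOX genes at -3.89, and ribosomal protein genes at -0.59, in 5 of 5 libraries each, with a median over all tested genes of -0.44. Bhlha15, a transcription factor gene of secretory cells, was at 5.60. B-lineage-like cells had HSC identity genes at -4.03 and inflammation and NF-kB genes at 1.28, with Cd40 at 5.86, but only 1 library held 5 cells of both classes (median over all tested genes -0.24). T-lineage-like cells had HSC identity genes at -2.45 and fatty acid genes at -0.90, in 5 of 5 libraries each, with Cd5 at 5.94 and a median over all tested genes of -0.18. Erythroid genes were called higher also in neutrophil-lineage-like cells (2.84), B-lineage-like cells (2.46) and megakaryocyte-lineage-like cells (1.72). For the neutrophil-lineage-like cells, every library compared is among 5 neighbouring ones, described below, where HSC-like cells carried high erythroid markers. In T-lineage-like cells they were at 1.94 over all cells, but at most at 0.61 in any of the 5 libraries, higher in only 2 of them, and at -0.040 with cells weighted equally. Cluster 8, with 212 unnamed cells, was led by predicted genes such as Gm10801 together with the muscle genes Acta1 and Myh4, and cluster 13, with 124 cells, by Pinlyp and Pstpip2. Procr was at 283 and 230 CPM in these.

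In the weighing below, the test for 2 cells in 1 tube, the bootstrap, the relations within libraries holding the source cells, the tests without a block of libraries and against the other marker set, the use of the unnamed erythroid cluster as a source and the seed comparison were chosen after results were seen. No biological explanation by month or tissue was tested. The marker relations were first computed with the looser HSC-like class, which on the cells used here gives rank correlations of 0.481 and -0.0668 over 62 libraries.

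Neutrophil marker genes summed to a library median of 1344 CPM in HSC-like cells of 48 libraries without neutrophil-lineage-like cells and 1731 CPM in 13 libraries with them, against 87672 CPM in the neutrophil-lineage-like cells. Over the 61 libraries the level had a Spearman rho of 0.478 with the share of counts held by those cells (Pearson r 0.645), and within the 13 libraries of 0.731. Libraries are not replicates, and 5 neighbouring ones carry much of this, with neutrophil markers at 1917 to 4111 CPM. Without them rho was 0.262, and 0.119 within the other 8 libraries that held such cells. Erythroid markers were high in the same 5 libraries (3194 to 5073 CPM, against a median of 1784 CPM in the other 56). They followed the neutrophil share as well (rho 0.551). Outside these 5, neutrophil markers reached 2045 CPM and erythroid markers 3389 CPM, so the ranges overlap. Reads moved between barcodes of a pool therefore cannot be told apart from another difference between libraries. The ratio of medians of 1.287 leaves low expression by the HSC-like cells themselves open. Erythroid markers had a rho of -0.043 with the share of counts held by the erythroid cluster (95% bootstrap interval -0.293 to 0.198) and of -0.138 within the 16 libraries that held its cells. In the earlier run with 17 further cells and a named erythroid class that last relation was strongly negative, so it is unstable. A rule that such a negative relation excludes moved reads was added after that run and applies to no value here. The bootstrap interval resamples libraries, which are not replicates. Its upper end of 0.198 lies under the rho set beforehand for moved reads, but above the rho set for their absence. The erythroid markers were at only 13465 CPM in the erythroid cluster. In HSC-like cells their library medians were 1764 CPM with and 1892 CPM without cells of that cluster. Because this contrast is small and 45 of the 61 libraries held no such cells, moved reads cannot be told apart from none here. By the criteria written before the results, the neutrophil rho of 0.478 counted for moved reads and the erythroid rho of -0.043 against them. Checks added later left both open.

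The Jchain cluster was weighed as 2 cells in 1 tube. Mecom, Hlf and Esam had a median log2 ratio of -4.76 to HSC-like cells, far below the level that 1 HSC-like partner would leave, which argues against such a partner. Antibody-secreting cells in the sorted gate are a candidate explanation: 10 of 10 secretory genes such as Xbp1, Irf4 and Prdm1 were higher, with a median fold of 27.34. Partners of other classes were not tested.

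Cluster 11, with 129 cells of which 93 came from 3 libraries, was led by the Y-linked gene Eif2s3y. Clustering without the Y-linked genes was a void test, since 0 of the 4 were among the clustering genes. For the same reason these genes themselves did not drive the cluster, a reading made after that was seen. A Y-linked count was present in 86.8% of its cells and in 87.0% of the other cells of those 3 libraries, and over libraries this share ran from 0 to 97.8%. All 3 belong to the 5 neighbouring libraries above, where neutrophil and erythroid markers were high. There S100a8 was at 1640 CPM in the 93 cells and already at 874 CPM in the 71 HSC-like cells, and in the other libraries at 378 CPM in 36 cells of the cluster and 52.4 CPM in HSC-like cells, a comparison chosen after the values were seen. Other differences between animals or libraries stay open, untested, and with seed 1 its best-matching cluster overlapped it with a Jaccard index of 0.790.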
